A study of Mus musculus with 3 samples.

How the data were processed

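RNA was measured by sequencing of polyadenylated RNA from 3 libraries of mouse bone-marrow-derived macrophages, 1 per biological replicate, at 1 dose and 1 time. Per the labels, 1 µg of starting RNA was used and the size range was 250 to 400. Mean fragment lengths, read from the deposited effective lengths, were 259, 289 and 287 bases in replicates 1, 2 and 3. Per the readme deposited with each sample, reads were quantified on assembly mm10 with GENCODE annotation M21. Programs, versions and the aligner are not given in the sources used here. Per the file headers, each library had a gene-level table and a matching transcript table made from a transcriptome alignment. Their expected counts, per the file headers, are fractional counts assigned by a model, with no scaling between libraries. The deposited TPM values sum to the same total in every library, and the deposited FPKM values are divided by effective length and library total. The deposited percent values give the share of a gene's TPM on each transcript. A second transcript quantification of the same libraries, made without an alignment file, gave estimated counts and TPM, per the file headers. Its transcripts were summed per gene.

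Each gene table held 55536 gene entries, of which 55450 had a name. The 86 without a name were kept under their identifiers. Entries without a gene identifier were left out of library totals: 26248 numbered entries, which held no counts, 96 ERCC spike-in sequences and the phiX genome. Totals on gene entries were 26.6e6, 34.3e6 and 48.4e6 expected counts. A share of counts in 1 library is given with its 95% Wilson interval. A gene without counts is given its floor, the TPM that 3 counts would make in the library where that is highest. In all, 17285, 17618 and 18254 genes had counts.

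All 3 libraries form 1 group, so no test between groups was made, no outlier test was applied to 3 samples, and correlations across samples were not computed. The 37 gene lists (459 genes), 20 gene pairs and 8 list pairs, the tests, their thresholds and the rule for named genes were chosen before the data were examined. The rule names up to 4 members with the highest and up to 2 with the lowest mean TPM of each list, both genes of each pair, the 10 nuclear genes with the highest mean TPM and the 10 with the largest dispersion. It adds every sex-linked gene and, for isoforms, the 5 most abundant genes with the same and with different choices. Some genes that meet the rule are not reported here. The neutrophil genes Ltf and Camp, the RNAs without a poly(A) tail and the gene families of the closing part were chosen after their values were seen.

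List levels are medians of log2(mean TPM + 0.1) over all members, set against 10000 random lists from genes with any count. Members without counts had first been left out and were restored to this definition after levels had been seen. List pairs were compared by a two-sided test that permutes the list labels of the genes 100000 times, Benjamini-Hochberg adjusted over 8 pairs. Genes within a list are not independent, so these p-values describe these libraries only. Gene pairs count as apart when 3 of 3 libraries have the same sign and the mean exceeds 2 SD. Variation between libraries was tested per gene with a chi-square test with 2 degrees of freedom on rounded expected counts after TMM scaling, for genes with a mean count of at least 10, Benjamini-Hochberg adjusted at 0.05. Dispersions came from edgeR with an intercept only. List variability was set against 10000 random lists matched in 20 bins of mean count. Software was R 4.3.3, edgeR 4.0.16, limma 3.58.1, DESeq2 1.42.0, Python 3.11.15, numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9.

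The tests of varying genes, list levels, list pairs and list variability and the coefficient of variation were run on simulated data with known answers. The gene pair rule, the 2-fold counts and the isoform comparison were not simulated. Of genes set 1.5-fold or 2-fold apart in 1 library, 71% and 78% of 100 each were recovered, and with a mean count of at least 100, 90.8% of 76 and 100.0% of 71 were. A first requirement, over 80% recovery of 2-fold differences at a mean count of 10 or more, was not met. It was replaced, after this was seen, by a requirement on genes with a mean count of at least 100, so recovery is given for both sets. Of 12260 unchanged genes, 0.0734% were called. These simulated counts were whole numbers, tested with the library totals used to draw them. TMM scaling and counts assigned by a model were thus not covered by these rates. A simulated coefficient of variation of 20% was estimated as 20.1%. Random lists were called high or low in 5.0% and more variable in 3.0% of draws. For the latter, all genes were simulated with the same coefficient of variation, 20%. List pairs from the same distribution had a permutation p under 0.05 in 5.25% of draws, and pairs set 16-fold apart in 97%. Alternatives covered pseudocounts, count and TPM minimums, total-count and DESeq2 scaling, FPKM, the second quantification, means in place of medians, other thresholds and leaving out each replicate.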

Results

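Polyadenylated RNA was sequenced from macrophages grown from the bone marrow of C57BL/6J mice and stimulated at 100 ng/mL for 480 minutes. The labels disagree on the stimulus: the sample descriptions name lipid A, the lipid part of bacterial lipopolysaccharide that activates Toll-like receptor 4, and the treatment fields name lipoprotein A. The series held 1 group of 3 biological replicates from separate biosamples, here called replicates 1, 2 and 3. No untreated macrophages were among the samples, so the values are levels after stimulation and say nothing on change from rest. The gene-level tables held 26589042, 34344922 and 48356527 expected counts on gene entries in replicates 1, 2 and 3. Levels below are the deposited TPM values, transcript abundances scaled to the same library total, as mean ± SD over the libraries (SD, n = 3) unless a replicate is named. A gene counted as detected when it reached 1 TPM in all 3 libraries, which 9930 genes did. Of these, 9239 were protein-coding, 101 were long intergenic noncoding and 102 were antisense genes. Coordinates are on mouse assembly mm10.

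The most abundant nuclear transcripts came from iron storage, chemokine, lysosomal, antigen presentation and cytoskeletal genes. Fth1, the ferritin heavy chain (ENSMUSG00000024661.7, chromosome 19, 9980598 to 9985098), stood at 35809 ± 7705 TPM (SD, n = 3), and the light chain Ftl1 (ENSMUSG00000050708.16, chromosome 7, 45457944 to 45459884) at 10316 ± 705 TPM. Ccl5, a chemokine that recruits T cells and monocytes (ENSMUSG00000035042.2, chromosome 11, 83525778 to 83530518), stood at 17129.9 ± 1706 TPM. Lyz2, the lysozyme of myeloid cells (ENSMUSG00000069516.8, chromosome 10, 117277331 to 117282321), stood at 12916 ± 2539 TPM. B2m, the invariant chain of MHC class I (ENSMUSG00000060802.8, chromosome 2, 122147686 to 122153083), stood at 12081 ± 1809.6 TPM. The lysosomal genes Psap (ENSMUSG00000004207.14, chromosome 10, 60277627 to 60302597) and Ctsb (ENSMUSG00000021939.8, chromosome 14, 63122462 to 63145923) stood at 9573 ± 221 and 9348 ± 608 TPM. The actin gene Actb (ENSMUSG00000029580.14, chromosome 5, 142903115 to 142906754) and the actin-binding Tmsb4x (ENSMUSG00000049775.16, chromosome X, 167207093 to 167209315) stood at 12008 ± 2724 and 9428 ± 1829.9 TPM. The highest nuclear value, 36039 ± 24896 TPM, belonged to the ribosomal RNA gene CT010467.1 (ENSMUSG00000106106.2, chromosome 17, 39846353 to 39848827). It took 2.78% (95% Wilson interval 2.77 to 2.78) of the counts in replicate 1, 1.83% (95% Wilson interval 1.83 to 1.84) in replicate 2 and 6.66% (95% Wilson interval 6.66 to 6.67) in replicate 3. Such intervals, and the 3-count floors given below for genes without counts, cover counting error only.

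Genes that mark macrophages were expressed throughout. All 25 members of the macrophage identity list were detected, with a median of 1141 TPM and a sum of 71416 ± 901 TPM (SD, n = 3). Beside Lyz2 and Ctsb, the lipid carrier Apoe stood at 8735 ± 1212 TPM and the transmembrane glycoprotein Gpnmb at 7509.7 ± 1683 TPM. The integrin chain Itgam was among the lowest members at 65.1 ± 10.003 TPM. The list lay in the highest 2.5% of 10000 random gene lists of its size, which counted as a high level. Of the 37 lists, 20 were high, 6 were low, in the lowest 2.5%, and 11 lay between. The high lists were macrophage identity, interferon-stimulated genes, chemokines, cytokines, feedback regulators, the TLR4 pathway, other Toll-like receptors, NF-kB subunits, inflammasome components, the NADPH oxidase, classical activation effectors, MHC class I, MHC class II, glycolysis, respiration, sterol handling, antioxidant response, matrix remodelling, mitochondrially encoded and housekeeping genes. The percentiles of the high lists ran from 99 to 100. With protein-coding genes alone as the pool, an alternative chosen after the data were seen, all 11 lists between the thresholds had lower percentiles. Among them, alternative markers stood at 47.5, immediate early genes at 31.8 and the neutrophil list at 23.1. The interferon (2.34), T cell (2.37) and progenitor (2.14) lists were then low. Genes are not replicates, so the percentiles describe these libraries and are not p-values.

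Markers of most other blood and tissue cells were low or lay between the thresholds. Of the 12 lists for other cell types, 5 were low and none was high. No B cell marker was detected (0 of 8, percentile 0.78), and Cd79b, a chain of the B cell receptor, had the highest level at 0.847 ± 0.46 TPM (SD, n = 3). No NK cell marker was detected (0 of 7, percentile 0.29), with the granzyme Gzma highest at 0.0733 ± 0.127 TPM. No mast cell, basophil and eosinophil marker was detected (0 of 8, percentile 0). Prg2, an eosinophil granule protein, had 27 counts in replicate 2 and 0 in the other libraries. No epithelial marker was detected (0 of 6, percentile 0), and the keratins Krt8, Krt18 and Krt19 had no counts, with floors of 0.102, 0.147 and 0.239 TPM in the library with the highest floor. Of the erythroid and megakaryocyte list, 1 of 10 members was detected (percentile 0.99). That member, the platelet chemokine Pf4, stood at 228, 859 and 223 TPM in replicates 1, 2 and 3. No fibroblast and stromal marker was detected (0 of 9, percentile 16.8), and the collagen gene Col1a1 stood at 0.257 ± 0.191 TPM. No haematopoietic progenitor marker was detected (0 of 7, percentile 6.64), and the transcription factor gene Myb stood at 0.523 ± 0.499 TPM.

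The T cell, dendritic cell, endothelial, osteoclast and neutrophil lists lay between the thresholds. Of the T cell list, 3 of 9 members were detected (percentile 11.8). These were the coreceptor gene Cd4 at 34 ± 5.28 TPM, the kinase gene Lck at 22.1 ± 9.08 TPM and the costimulatory receptor gene Cd28 at 11.1 ± 2.65 TPM (SD, n = 3). The T cell receptor complex genes Cd3d and Cd3g had no counts (floors 0.349 and 0.162 TPM), and Cd3e had 3 counts in replicate 2 alone. Of the dendritic cell list, 2 of 8 members were detected (percentile 29.4), with the actin-bundling gene Fscn1 at 32.9 ± 13.1 TPM. The endothelial list had 3 of 6 detected members (percentile 31.7), led by the VEGF receptor gene Kdr at 53.2 ± 22.2 TPM. The osteoclast list had 3 of 8 detected members (percentile 37.3), led by the phosphatase gene Acp5 at 130.3 ± 68.8 TPM, and 6 of its members were highest in replicate 2. The neutrophil list had 3 of 11 detected members (percentile 59.4), and 10 of its 11 members were highest in replicate 2. For reference, 7 of 12 housekeeping genes were highest in replicate 2. The calprotectin gene S100a9 stood at 14.8, 237 and 12.4 TPM in replicates 1, 2 and 3, and its partner S100a8 at 6.48, 128 and 6.72 TPM. Ngp, a neutrophil granule gene, stood at 0.96, 43.3 and 1.0 TPM. Without replicate 2, the T cell percentile was 0.11 and the progenitor percentile 1.72, both in the low range. The neutrophil percentile was 24.7 there, between the thresholds. Among genes with a mean count of at least 10, the T cell, progenitor and fibroblast percentiles were 77.3, 0.64 and 0.12, the latter 2 in the low range. Members with fewer counts are left out there, and 3 of 9, 3 of 7 and 4 of 9 members had such counts. The T cell value thus rests on the few members that were expressed.

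The labels give no sex for the donors. Among the 6 sex-linked genes, Xist, the RNA of the inactive X chromosome, stood at 37.1 ± 6.26 TPM (SD, n = 3). The Y-linked genes Ddx3y and Eif2s3y each had 1 count, in replicate 2, and Kdm5d and Uty had none, with floors of 0.050 and 0.0638 TPM. Tsix, the antisense partner of Xist, had no counts (floor 0.0491 TPM). The list was low, at percentile 0, and at percentile 5.07 in the second quantification of the same libraries, where it was not low.

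**Figure D1:**
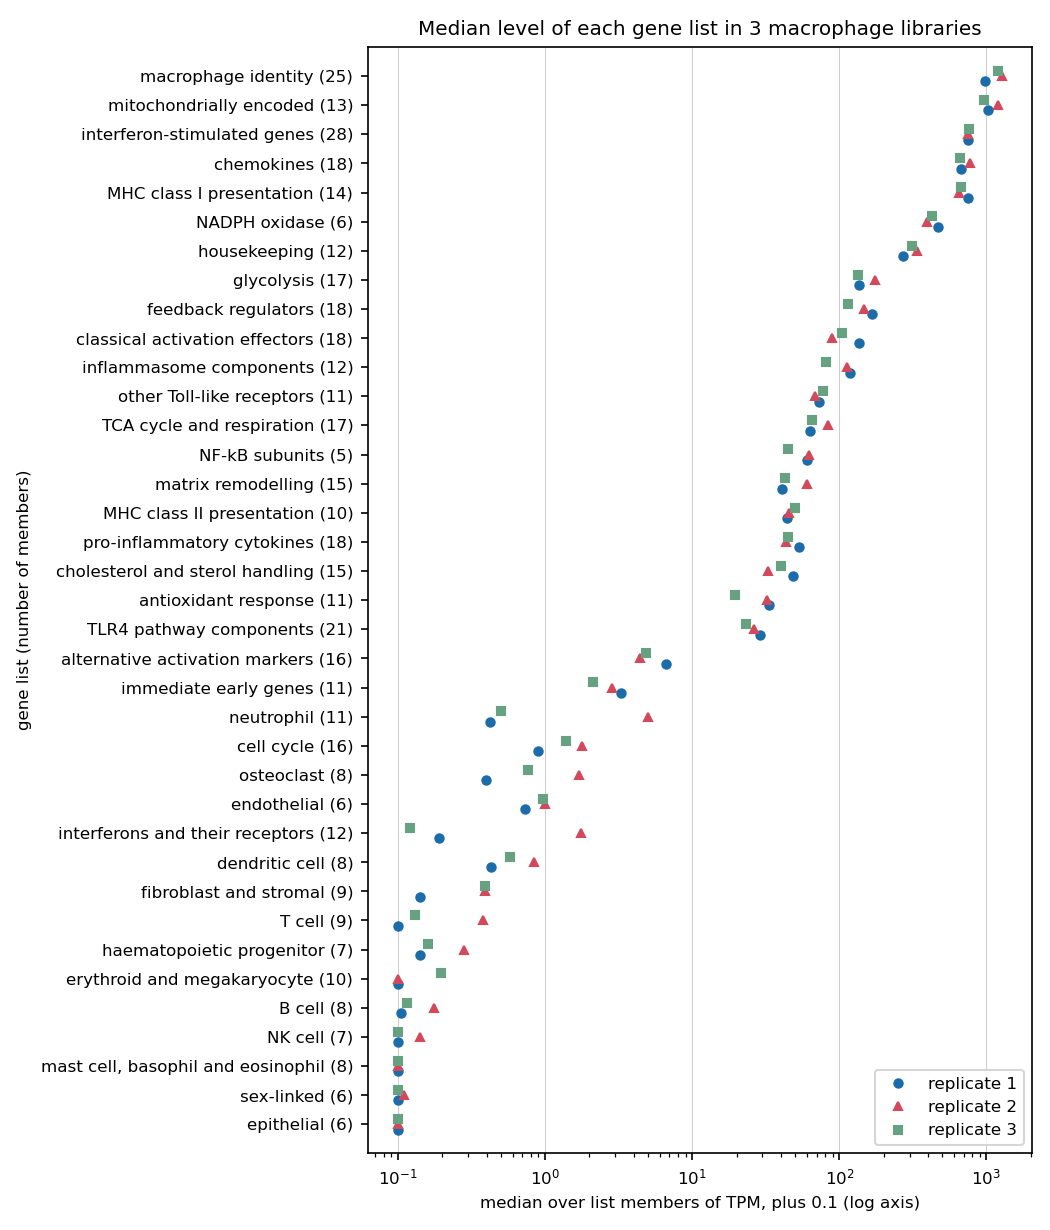
Each point is the median TPM of a gene list in 1 of the 3 libraries, plus 0.1, on a log axis, with the lists ordered by their median and their number of members in brackets. Macrophage identity has the highest median over the libraries, 1141 TPM, interferon-stimulated genes have a median of 753 TPM, and the epithelial list sits at 0 TPM.

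Interferon-stimulated genes were expressed throughout. All 28 members were detected, with a median of 753 TPM and a sum of 39502 ± 558 TPM (SD, n = 3). The antiviral enzyme gene Rsad2 stood at 5603 ± 285 TPM, the ubiquitin-like modifier Isg15 at 4127 ± 420.5 TPM, the antiviral RNA-binding Ifit2 at 4076 ± 581 TPM and the GTPase gene Gbp2 at 2793 ± 64 TPM. The lowest members were the RNA sensor Oas2 at 151 ± 36.9 TPM and Irf9, the DNA-binding part of the interferon transcription complex, at 62.5 ± 4.92 TPM. Among the interferon genes, Ifnb1, the interferon made early after pattern recognition, stood at 6.37 ± 1.16 TPM, and the type III genes Ifnl2 and Ifnl3 had no counts (floors 0.39 and 0.533 TPM). The receptor chains Ifnar2, Ifngr2, Ifnar1 and Ifngr1 stood at 174 ± 5.71, 146 ± 16.9, 106 ± 10.9 and 24.2 ± 3.37 TPM. Together, 5 of 12 interferon and receptor genes were detected, at percentile 16.6. That percentile depended on the setting. It was 0.47, in the low range, without replicate 2, and 97.4, short of the high range, among genes with a mean count of at least 10, where members with fewer counts are left out.

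Chemokines and inflammatory cytokines were both expressed, with chemokines at the higher level. Of the 18 chemokines, 16 were detected, with a median of 707 TPM. Beside Ccl5, Cxcl10, which attracts activated T cells, stood at 7072 ± 733 TPM, and Ccl4 and Ccl3, which recruit macrophages and T cells, stood at 2429.9 ± 551 and 2181 ± 531 TPM (SD, n = 3). Ccl17 and Cxcl3 were lowest at 1.09 ± 0.971 and 0.64 ± 0.534 TPM. Of the 18 cytokines, 13 were detected, with a median of 45.4 TPM. Il1b stood at 775 ± 416 TPM, Tnf at 681 ± 193 TPM, the lymphocyte growth factor Il15 at 468 ± 8.97 TPM and Ebi3, a subunit of IL-27, at 420.4 ± 117 TPM. Csf2 and Il23a were lowest at 0.113 ± 0.0551 and 0.103 ± 0.0666 TPM, from 1 to 3 counts per library. By library, Il1b stood at 869.8, 1136 and 319.8 TPM and Tnf at 782, 802 and 459 TPM in replicates 1, 2 and 3. Medians of log2 TPM differed by 3.84 ± 0.30 (SD, n = 3) between chemokines and cytokines, chemokines higher in 3 of 3 libraries, with an adjusted p = 0.0268 from permutation of the list labels of the genes. With members of at least 1 TPM only, the difference was 2.80 and the permutation test no longer passed (adjusted p = 0.0531).

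Interferon-stimulated genes lay above the cytokines by 4.06 ± 0.22 log2 units (SD, n = 3) in 3 of 3 libraries (permutation adjusted p = 8e-05, from a p of 1e-05 that is the smallest the permutations can give). Their distance from the immediate early genes was larger, 8.13 ± 0.34 log2 units in 3 of 3 libraries (n = 3, permutation adjusted p = 8e-05). Of the 11 immediate early genes, which are induced within the first hour of many stimuli, 7 were detected, with a median of 2.65 TPM at percentile 68.1. The AP-1 genes Junb, Jun and Fos stood at 223 ± 59.4, 73.1 ± 26.9 and 18.8 ± 1.81 TPM (SD, n = 3), and Ier2 at 22.8 ± 8.52 TPM. Fosb and Fosl1 were lowest at 0.11 ± 0.0361 and 0.107 ± 0.185 TPM, from at most 9 counts in a library.

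Genes that restrain inflammatory signalling were all detected (18 of 18), with a median of 143 TPM. Il1rn, the antagonist of the IL-1 receptor, stood at 1968 ± 193 TPM, Tnip3, an inhibitor of NF-kB signalling, at 862 ± 275 TPM, Nfkbia, which holds NF-kB in the cytoplasm, at 615 ± 129 TPM and the repressor Atf3 at 384 ± 31.9 TPM (SD, n = 3). The cytokine signalling inhibitor Socs1 and the kinase-like inhibitor Irak3 were lowest at 36.4 ± 11.1 and 31.4 ± 9.58 TPM. The medians of feedback regulators and cytokines differed by 1.63 ± 0.17 log2 units (n = 3, permutation adjusted p = 0.121), higher in 3 of 3 libraries but short of the threshold. With means in place of medians the difference was 2.91 and passed the permutation test (adjusted p = 0.0171), and with members of at least 1 TPM only it was -0.00.

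Parts of the Toll-like receptor 4 pathway were all detected (21 of 21), with a median of 26.8 TPM. The co-receptor Cd14 stood at 756 ± 102 TPM, the kinase gene Ikbke at 349 ± 86.3 TPM, the transcription factor gene Irf5 at 241 ± 31 TPM and the adaptor Myd88 at 230.3 ± 20.1 TPM (SD, n = 3). The ubiquitin ligase gene Traf6 and the adaptor Traf3 were lowest at 6.79 ± 1.09 and 5.46 ± 0.18 TPM. Of the other Toll-like receptors, 9 of 11 were detected, with a median of 74.1 TPM. Tlr1, Tlr7, Tlr3 and Tlr2 stood at 249 ± 16.3, 203 ± 13.2, 143 ± 21.6 and 86.4 ± 4.81 TPM, and Tlr12 and Tlr5 at 0.317 ± 0.112 and 0.0633 ± 0.0404 TPM. The median of the pathway list minus that of the receptor list was -1.48 ± 0.22 log2 units (n = 3), lower in 3 of 3 libraries but not past the threshold (permutation adjusted p = 0.309). With means in place of medians the sign turned to 0.83 (permutation adjusted p = 0.429).

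All 5 NF-kB subunits were detected, at percentile 99. Nfkb2 and Nfkb1 stood at 308 ± 79.2 and 168 ± 16.6 TPM, Relb and Rela at 54.1 ± 12.6 and 49.2 ± 3.91 TPM, and Rel at 18.7 ± 1.82 TPM (SD, n = 3). Of the inflammasome components, 11 of 12 were detected, with a median of 104 TPM. The inflammatory caspases Casp1 and Casp4 stood at 532 ± 42.1 and 388 ± 39.9 TPM, the pore-forming Gsdmd at 302 ± 34.9 TPM and Casp8 at 174 ± 14.3 TPM. The sensors Nlrc4 and Nlrp1b were lowest at 3.38 ± 0.171 and 0.88 ± 0.39 TPM. All 6 genes of the phagocyte NADPH oxidase, which makes superoxide, were detected with a median of 431 TPM. Its membrane subunits Cyba and Cybb stood at 1465 ± 115 and 820.3 ± 73.6 TPM, and the GTPase gene Rac2 at 504 ± 91.3 TPM. Among genes with a mean count of at least 10, the NF-kB percentile was 96.3, which is not in the high range.

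Effectors of classical activation lay above markers of alternative activation. Of 18 classical effectors, 17 were detected, with a median of 129 TPM, against 10 of 16 alternative markers with a median of 5.05 TPM (percentile 83.3). The acute phase gene Saa3 stood at 5649.6 ± 3153 TPM, Acod1, which makes itaconate, at 3264 ± 558 TPM, the costimulatory receptor Cd40 at 1423 ± 373 TPM and the mitochondrial superoxide dismutase gene Sod2 at 1364 ± 184 TPM (SD, n = 3). Cd80 and the tryptophan-degrading Ido1 were lowest at 13 ± 0.91 and 0.487 ± 0.405 TPM. Among alternative markers, the IL-4 receptor chain Il4ra stood at 201 ± 66.7 TPM, the transglutaminase gene Tgm2 at 192 ± 32.8 TPM, the beta-glucan receptor Clec7a at 179.9 ± 65.4 TPM and the mannose receptor Mrc1 at 84.7 ± 22.5 TPM. Arginase 1 (Arg1) had 4 counts in replicate 3 and none in the other libraries, and Retnla had no counts (floor 0.507 TPM). The lists differed by 4.56 ± 0.16 log2 units (n = 3), classical effectors higher in 3 of 3 libraries (permutation adjusted p = 0.0018). Of the 18 classical effectors, 11 were highest in replicate 1, and of the 16 alternative markers, 8 were highest in replicate 2. Of the 12 housekeeping genes, 2 were highest in replicate 1 and 7 in replicate 2, so the alternative markers did not stand out there.

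Presentation through MHC class I was expressed above presentation through class II. All 14 class I genes were detected, with a median of 689.9 TPM. Beside B2m, the heavy chains H2-K1 and H2-D1 stood at 5187 ± 458 and 4409 ± 535 TPM and the proteasome activator Psme2 at 1498 ± 30.01 TPM (SD, n = 3). Tapbpl and the trimming peptidase Erap1 were lowest at 66.4 ± 6.72 and 47.5 ± 4.02 TPM. Of the 10 class II genes, 7 were detected, with a median of 46.5 TPM. The invariant chain Cd74 stood at 519 ± 107 TPM, H2-Aa at 199.8 ± 19.1 TPM, H2-Ab1 at 154 ± 13 TPM and H2-Eb1 at 125 ± 15.2 TPM. The peptide-loading regulators H2-Oa and H2-Ob were lowest at 0.72 ± 0.20 and 0.363 ± 0.22 TPM. The lists differed by 3.89 ± 0.18 log2 units (n = 3), class I higher in 3 of 3 libraries (permutation adjusted p = 0.0008). With members of at least 1 TPM only, the difference was 2.46 and the permutation test no longer passed (adjusted p = 0.0531).

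Genes of glycolysis and of mitochondrial respiration were all detected, 17 of 17 and 17 of 17. Medians were 150.4 TPM for glycolysis and 70.6 TPM for the TCA cycle and respiration. Gapdh stood at 1060.1 ± 199.8 TPM, the hexokinase gene Hk3 at 749 ± 52.7 TPM, Aldoa at 381 ± 65.8 TPM and Pkm at 351 ± 41.3 TPM, with the glucose transporter Slc2a1 and the phosphofructokinase Pfkl lowest at 18.7 ± 3.63 and 17.9 ± 3.71 TPM (SD, n = 3). In the respiration list, Cox4i1, Atp5b and Cox5a stood at 517 ± 79, 496 ± 85.8 and 391 ± 65 TPM, and the TCA cycle enzymes Idh3a and Fh1 were lowest at 10.1 ± 4.55 and 6.52 ± 0.943 TPM. The medians differed by 1.06 ± 0.03 log2 units (n = 3), glycolysis higher in 3 of 3 libraries, which did not pass the permutation test (adjusted p = 0.231). In replicate 2, where 10 of 11 neutrophil genes were highest, 16 of 17 respiration genes and 11 of 17 glycolysis genes were highest too. So were 7 of 12 housekeeping genes.

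Sterol genes were all detected (15 of 15), with a median of 39.1 TPM. The cholesterol exporter Abcg1 stood at 152 ± 9.53 TPM, the oxysterol receptor gene Nr1h3 at 118 ± 27.1 TPM and the cholesterol-esterifying Soat1 at 117 ± 21.3 TPM (SD, n = 3). The synthesis gene Lss was among the lowest at 5.38 ± 1.76 TPM. Of the sterol genes, 10 were highest in replicate 1 and 3 in replicate 2. The antioxidant list, with 9 of 11 detected, was led by Fth1, followed by the peroxiredoxin Prdx1 at 1155 ± 278 TPM, the autophagy adaptor Sqstm1 at 233 ± 71.7 TPM and the haem oxygenase Hmox1 at 209 ± 10.4 TPM. Gclc, for glutathione synthesis, and the quinone reductase Nqo1 were lowest at 1.07 ± 0.389 and 0.737 ± 0.0651 TPM. Of the matrix remodelling list, 14 of 15 were detected, led by the collagenase gene Mmp13 at 544 ± 118 TPM and the membrane-bound Mmp14 at 488 ± 106 TPM, with Mmp9 lowest at 0.353 ± 0.316 TPM. Of these lists, 8 of 11 antioxidant and 10 of 15 matrix genes were highest in replicate 2, as were 7 of 12 housekeeping genes. Among genes with a mean count of at least 10, the antioxidant percentile was 95.4, which is not in the high range.

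Of the cell cycle list, 7 of 16 members were detected (median 1.22 TPM, percentile 49.6). The replication clamp Pcna stood at 276 ± 62.9 TPM, the helicase gene Mcm6 at 18.8 ± 6.19 TPM and the mitotic kinase Cdk1 at 8.14 ± 4.02 TPM, with the cyclin Ccna2 and the checkpoint kinase Bub1 lowest at 0.25 ± 0.195 and 0.25 ± 0.21 TPM (SD, n = 3). Of its members, 13 of 16 were highest in replicate 2. Among genes with a mean count of at least 10, the list was low (percentile 0.28). The housekeeping list was high with 12 of 12 detected, from Actb at 12008 ± 2724 TPM and Eef1a1 at 3207 ± 428 TPM to Tbp at 9.28 ± 0.29 TPM. Genes of the mitochondrial genome took 1.41% ± 0.105 of the counts (SD, n = 3), and 12 of 13 protein genes were detected. The short mt-Atp8 stood at 23329.6 ± 6629 TPM in the gene-level tables and 5191 ± 1008 TPM in the second quantification, and the oxidase subunit mt-Co1 at 7885 ± 619.8 TPM. The level of mt-Atp8 is uncertain, since 3 counts make up to 12.4 TPM for it, against 0.134 TPM for mt-Co1. It had 4851, 6922 and 10000 counts in replicates 1, 2 and 3, against 190633, 231552 and 295249 for mt-Co1. The lowest, mt-Atp6 and mt-Co3, at 187 ± 104 and 103 ± 148 TPM, are uncertain, since the second quantification gave 3081 ± 917 and 1692 ± 611 TPM.

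Ratios of 20 fixed gene pairs were taken within each library as log2 of TPM plus 0.1, and 17 pairs lay apart, with the same sign in 3 of 3 libraries and a mean beyond 2 SD. The nitric oxide synthase Nos2 (ENSMUSG00000020826.8, chromosome 11, 78920787 to 78960254), at 523 ± 20.2 TPM, lay above its arginine competitor Arg1 (ENSMUSG00000019987.9, chromosome 10, 24915221 to 24927484) by 12.02 ± 0.56 (log2, SD, n = 3). With a pseudocount of 1 that ratio was 8.99, and in the second quantification 11.40 ± 0.85, since Arg1 had almost no counts. The arginine transporter Slc7a2 lay above its relative Slc7a1 by 4.56 ± 0.26, at 27.4 ± 11 and 1.05 ± 0.365 TPM. The inducible cyclooxygenase Ptgs2, at 148 ± 45 TPM, lay above the constitutive Ptgs1, at 3.55 ± 0.549 TPM, by 5.30 ± 0.43. Cxcl10 lay above Cxcl9, at 224 ± 58.1 TPM, by 5.01 ± 0.53, and Ccl5 above the monocyte attractant Ccl2, at 1113 ± 132 TPM, by 3.95 ± 0.30. Irf7 (ENSMUSG00000025498.15, chromosome 7, 141262706 to 141266481), which amplifies interferon production, stood at 2414 ± 46.3 TPM and lay above Irf3, at 26.8 ± 5.06 TPM, by 6.50 ± 0.30. Isg15 exceeded Ifnb1 642-fold, a log2 ratio of -9.33 ± 0.19 for Ifnb1 over Isg15. In the second quantification it was -8.65 ± 0.06.

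Among cytokines, Il12b, the shared chain of IL-12 and IL-23, lay 6.90 ± 1.10 (log2, SD, n = 3) above Il12a, at 147 ± 71.5 and 1.23 ± 0.746 TPM. Tnf lay above the anti-inflammatory Il10, at 62.7 ± 8.22 TPM, by 3.40 ± 0.63. Il6, at 30.3 ± 11.2 TPM, over Tnf gave -4.52 ± 0.20, so Tnf was 22.9-fold higher. Il1b over Il1a, at 378 ± 283 TPM, gave 1.12 ± 0.47, and Il1a stood at 697 TPM in replicate 2 against 282 and 156 TPM in replicates 1 and 3. Without division by length the Il1b ratio was 0.46 and did not pass, and without replicate 3 it was 1.17 and did not pass. Nfkbia and Nfkb2 lay above Nfkb1 by 1.85 ± 0.17 and 0.84 ± 0.28. Socs3, at 375 ± 17.5 TPM, lay above Socs1 by 3.41 ± 0.38, and Tlr2 above Tlr4, at 29.7 ± 4.05 TPM, by 1.54 ± 0.21. The costimulatory ligand Cd86, at 139 ± 40.4 TPM, lay above Cd80 by 3.37 ± 0.37. The hexokinase Hk2, at 24.6 ± 4.48 TPM, over Hk1, at 112 ± 14.5 TPM, gave -2.19 ± 0.16, and -2.94 ± 0.14 in the second quantification.

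The other 3 pairs kept their sign in 3 of 3 libraries but not by 2 SD. Il1rn over Il1b gave 1.53 ± 0.90 and Il12b over Il10 gave 1.13 ± 0.81 (log2, SD, n = 3). The scavenger receptor Marco, at 54, 36.6 and 7.87 TPM in replicates 1, 2 and 3, gave -1.72 ± 1.57 over Mrc1. Without division by length these ratios were 2.15, 1.75 and -3.61, and all 3 pairs then lay apart. Il1rn over Il1b also lay apart without replicate 3, at 1.01, and Il12b over Il10 without replicate 2, at 0.66. An exact sign-flip permutation test on 3 libraries cannot give a p below 0.25 in any pair, two-sided, and gave 0.25 in all 20.

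**Figure D2:**
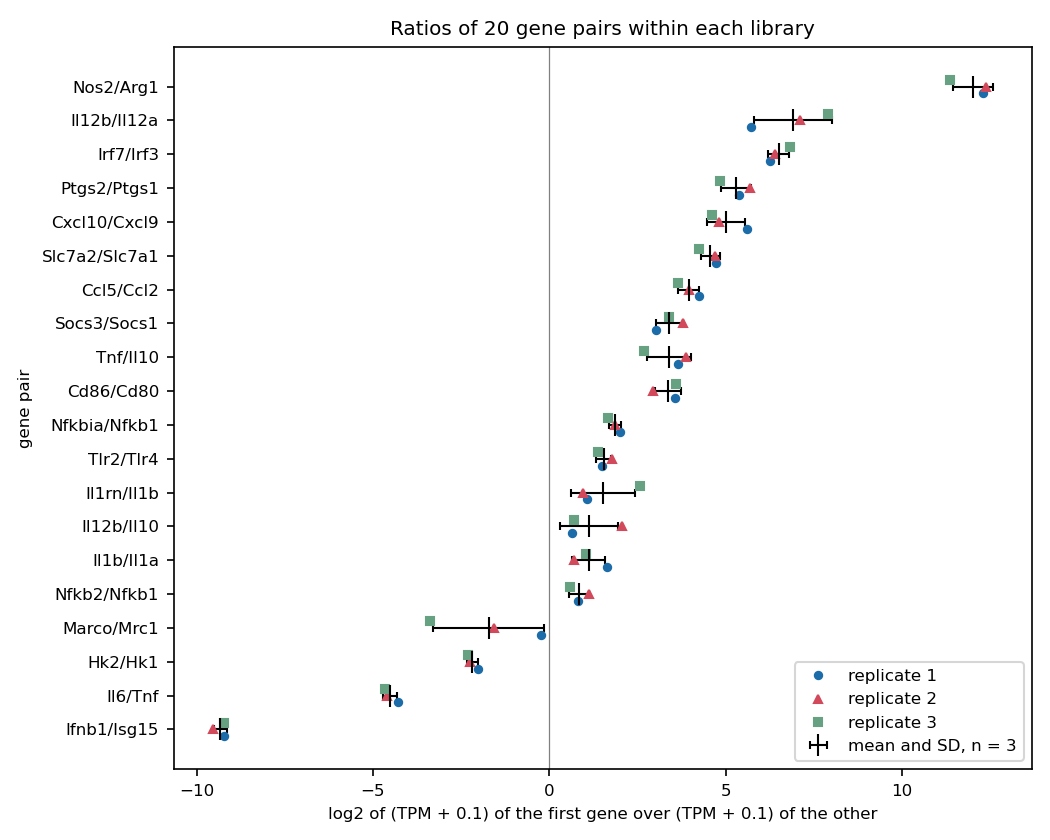
Points are log2 ratios of TPM plus 0.1 of the first gene over the other in each of the 3 libraries, and bars are their mean and SD. Nos2 over Arg1 sits highest at 12.02 and Ifnb1 over Isg15 lowest at -9.33, while Marco over Mrc1 spreads most, with an SD of 1.57.

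Variation between the replicates was set against counting error, which separate biological replicates exceed readily at this depth. Of 12414 genes with a mean expected count of at least 10, 8797 (70.9%) varied between the 3 libraries in a chi-square test on TMM-scaled counts at an adjusted p under 0.05. Without replicate 2 the count was 5203. The common biological coefficient of variation from edgeR was 23%. Among 9075 genes with a mean count of at least 100, 476 differed 2-fold or more between replicates 1 and 2, 250 between replicates 2 and 3, and 124 between replicates 1 and 3. Of the 476, 262 were higher in replicate 1 and 214 in replicate 2. With a 1.5-fold limit the numbers were 1809, 1136 and 669.

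The 10 genes with the largest edgeR dispersion included genes of the neutrophil list and genes whose sequence is shared with others. Ngp, S100a8 and S100a9 were highest in replicate 2, with biological coefficients of variation of 105%, 87.1% and 84.4%. Steap4, a metalloreductase, stood at 3.74, 0.33 and 2.39 TPM in replicates 1, 2 and 3. For the others, at least 50% of the stretches of 31 bases in their transcripts also occurred in transcripts of another gene, so their values are uncertain. These were AY036118, which lies inside CT010467.1, at 2743, 0 and 0 TPM, B430305J03Rik at 0, 0 and 6.04 TPM, Gm26778 at 0, 10.2 and 4.53 TPM, mt-Co3 at 273, 0.31 and 34.8 TPM, mt-Co2 at 874, 58.5 and 33.7 TPM and 1 of 2 genes named Chtf8 (ENSMUSG00000117748.1) at 1.92, 3.35 and 11.1 TPM.

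Gene groups differed in how much they varied between replicates. Of 31 lists with members of enough counts, 15 had a median biological coefficient of variation in the highest 2.5% of lists matched on expression. The neutrophil list stood at 85.8% against 22.6% in matched lists, at percentile 100. Classical effectors stood at 24.4% against 16.8% (percentile 100), sterol genes at 21.7% against 16.5% (100), cytokines at 24.1% against 17.3% (99.99) and chemokines at 21.3% against 17.2% (99.99). The dendritic cell (99.97), osteoclast (99.95), matrix (99.93), fibroblast (99.92), feedback (99.37), cell cycle (99.09), alternative (98.9), immediate early (98.9), mitochondrial (97.7) and antioxidant (97.7) percentiles passed too. Interferon-stimulated genes (24.7), the TLR4 pathway (11.3) and the NADPH oxidase (0.84) did not. Without replicates 1, 2 and 3 in turn, 10, 13 and 8 lists passed. Of the 15, the classical, matrix and dendritic cell lists passed in each of these settings. Without replicate 1 the fibroblast (20.1), cell cycle (40.6), mitochondrial (89.9), osteoclast (91.9), feedback (93.9), antioxidant (95.6) and alternative (95.8) lists did not pass. Without replicate 2 the neutrophil (23.4), alternative (78), sterol (90.8), chemokine (90.9) and cell cycle (95.5) lists did not. Without replicate 3 the mitochondrial (53.2), alternative (89.9), immediate early (92.9), cytokine (93.9), feedback (96), cell cycle (96.4) and antioxidant (97.4) lists did not. In the second quantification the mitochondrial (93.6), antioxidant (93.9) and cell cycle (95.3) lists did not.

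**Figure D3:**
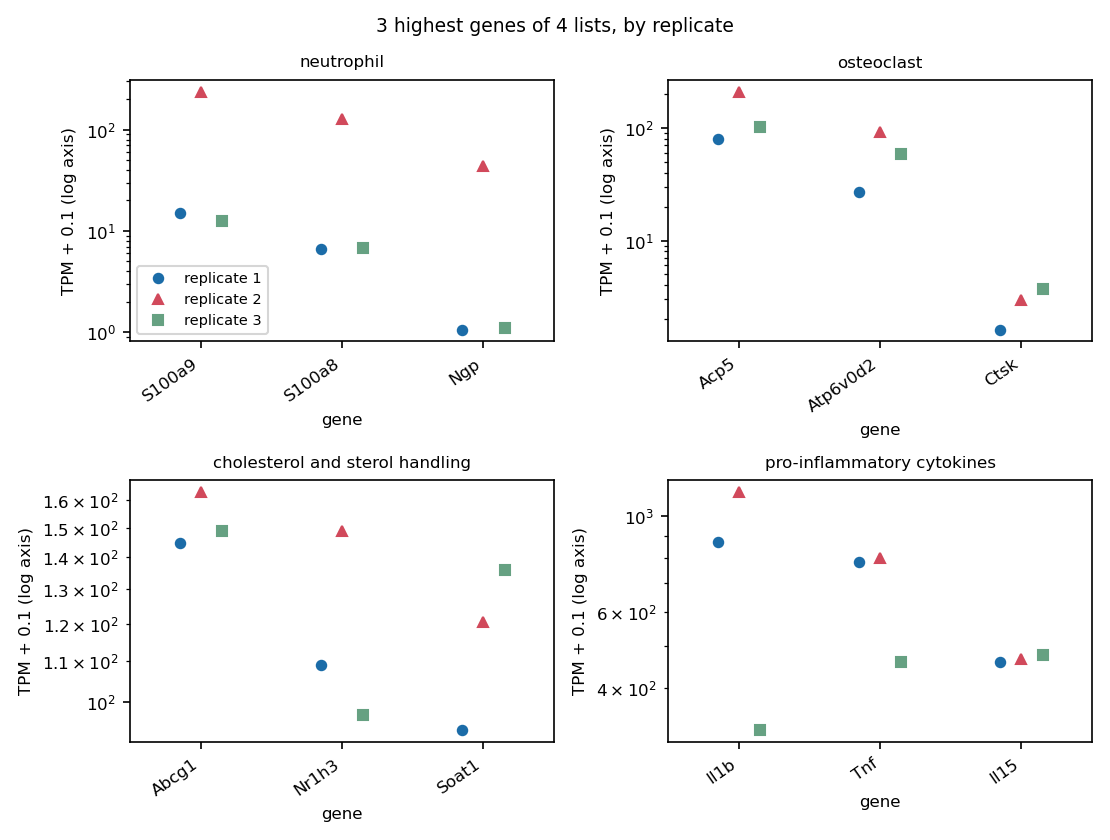
Points are TPM plus 0.1 in each of the 3 libraries, on log axes, for the 3 highest genes of 4 lists. S100a9 sits at 237 TPM in replicate 2 against 14.8 and 12.4 TPM, and Il1b at 319.8 TPM in replicate 3 against 869.8 and 1136 TPM.

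The transcript carrying most of a gene's signal was the same in both transcript quantifications of the libraries for 235 of 251 listed genes with at least 10 TPM and 2 or more annotated transcripts. For Fth1, Ccl5 and Actb it took 98.8% ± 0.243, 99.3% ± 0.080 and 98.6% ± 0.285 of the gene (SD, n = 3), and for Gpnmb 70.3% ± 13.2. For Apoe a transcript annotated as processed, without a coding sequence, took 63.2% ± 6.38. The most abundant genes with different choices included Ctsb, Cd40, Ywhaz and Ifih1. For Ctsb the gene-level program gave 58% ± 4.22 to a coding transcript, and the second quantification gave 52.1% ± 4.26 to a transcript with a retained intron. For Cd40 the shares were 34.6% ± 4.04 for 1 coding transcript and 31.4% ± 1.73 for another.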

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

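Signal outside the gene entries was set against the 3 counts that a count of 0 allows. The phiX genome, a bacteriophage used as a sequencing control, held 33907, 27439 and 32996 expected counts in replicates 1, 2 and 3. These were 0.127% (95% Wilson interval 0.126 to 0.129), 0.0798% (95% Wilson interval 0.0789 to 0.0808) and 0.0682% (95% Wilson interval 0.0675 to 0.0689) of all counts. The ERCC spike-in sequences held 0 counts in each gene table, but 5 and 4 estimated counts in the second quantification of replicates 1 and 2, above that limit, and 2 in replicate 3, below it. Beyond these, 3 patterns were weighed, and no biological explanation was tested, since there is 1 group. The tests of sequencing depth and of GC content and length were chosen after their pattern but before their results were seen. The tests of added RNA, neutrophil genes, shared sequence, RNAs without a poly(A) tail and the ribosomal locus were chosen after the values they rest on were seen.

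Replicates 1 and 2 differed 2-fold or more at 476 genes, against 124 between replicates 1 and 3. Unequal depth and trends with GC content or transcript length are argued against, since 493 genes against 125 remained after thinning to the smallest library, and 463 against 118 after the trends were removed. RNA of another cell type as the whole cause is argued against too, because 95 genes lay 2-fold or more below both others in replicate 2, against 28 in replicate 1 and 17 in replicate 3, a comparison set after the values were seen. RNA of granulocytes or their precursors as part of the cause stays open: that 10 of 11 neutrophil genes were highest in replicate 2 is the pattern and no test of it, with S100a9 at 237 TPM, Ltf at 6.44 against 0.32 and 0.83 TPM, and Camp at 4.87 against 0.35 and 0.40 TPM. Mature neutrophils are poorly supported, since Retnlg had 1 count and Ly6g 2 in replicate 2, so these members, Elane (6 counts) and Mpo (28 counts) add little to the 10, and culture differences stay untested.

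Of the 10 genes with the largest dispersion, 6 shared at least 50% of their stretches of 31 bases with another gene, against 9 of 100 genes matched on mean count. Reads divided differently among near-identical genes may underlie some of these values, which stays open. Summing counts with those genes cannot test this, since the partners carry most of the counts. For mt-Co3 the deposited posterior SDs of the counts, 2830, 4487 and 4578 in replicates 1, 2 and 3, exceeded the counts themselves. The second quantification gave it 2223, 1829 and 1024 TPM, and gave B430305J03Rik 0 TPM in each library. There AY036118, at 2011, 0 and 0 TPM, kept its pattern, and mt-Co2, Gm26778 and Chtf8 kept their order. Ngp, S100a8, S100a9 and Steap4 shared no such stretches, so this explanation does not reach them.

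The ribosomal RNA gene CT010467.1 took 6.66% of the counts in replicate 3, against 2.78% and 1.83% in replicates 1 and 2. Reads divided differently within the locus are argued against, since summed over its overlapping genes the share in replicate 3 was still 2.81 times the mean of the others. Less complete poly(A) selection in replicate 3 stays open for the difference from replicate 2. There 4 other RNAs without a tail had a median log2 ratio of -1.01 to replicate 2, and all 4 lay lower. By the limits set, a ratio of at least 1 for that cause and under 0.5 against it, this counted against it. However, all 4 were highest in replicate 2, where CT010467.1 had its lowest share. They thus did not follow the ribosomal RNA and cannot decide this. Counts were few for Rmrp (6, 33 and 38) and Rpph1 (15, 114 and 60) in replicates 1, 2 and 3. Against replicate 1 the median log2 ratio of the 4 RNAs was 0.95, from 0.40 to 1.83, short of the ratio of 1 set for that cause yet above 0.5. There too, less complete selection may or may not contribute. After its result was seen, that test was split by replicate, and Rn7s2, with the same counts as Rn7s1, was left out.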

How the results depend on the processing

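Of 137 recomputations of counts and list differences, 118 stayed on the same side of the threshold, within 1.5 times for counts or within 10% for the coefficient of variation, and 2 changed sign. Of 629 recomputations for single lists and gene pairs, 576 did, 28 lost and 25 gained a call, and none changed sign. The pool of protein-coding genes for list levels was added after seeing the data, and with it 9 lists were low. No paired analysis was possible because there is 1 group. The common coefficient of variation was 20.1% for genes with a mean count of at least 100 and 27.3% in the second quantification. Low lists numbered 3 among genes with a mean count of at least 10, where members under that count are left out: cell cycle (0.28), fibroblast (0.12) and progenitor (0.64). None of these was low before, and the 6 lists that were low had no value there. With members of at least 1 TPM, 3 of 8 list pairs passed: chemokines against cytokines gave 2.80 and MHC class I against class II 2.46 (permutation adjusted p = 0.0531 for both), and feedback regulators against cytokines changed sign at -0.00 (permutation adjusted p = 1). With means, the latter passed at 2.91 (permutation adjusted p = 0.0171), and TLR4 pathway against other Toll-like receptors changed sign at 0.83 (permutation adjusted p = 0.429). The cause was not tested.

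Genes at 2-fold or more between replicates 1 and 2, 2 and 3, and 1 and 3 numbered 1513, 976 and 701 with a mean count of at least 10, and 1809, 1136 and 669 at 1.5-fold. Leaving out each replicate gave 5203 (without replicate 2) to 7435 (without replicate 3) varying genes, a coefficient of variation of 17.5% (without replicate 2) to 27.5% (without replicate 3), and 8 (without replicate 3) to 13 (without replicate 2) more variable lists. With 2 libraries left, list variability kept the prior weight of the full fit. Depth limits genes without counts to floors that differ by gene, and the exact test of gene pairs cannot pass at 3 libraries.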

Other observations

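Gene families were summed as well, chosen after the values were seen, and some of their members, such as Gbp2, Gbp5, Slfn4, Ctsb, Ctsd and Ctss, are also in the fixed lists. Guanylate-binding proteins, interferon-inducible GTPases of cell-autonomous defence, were all detected (10 of 10) with a sum of 6341 ± 114 TPM (SD, n = 3), among them Gbp5 at 1425 ± 136 and Gbp6 at 544 ± 74.9 TPM. Immunity-related GTPases (8 of 8) summed to 3568 ± 359.9 TPM, with Irgm1 at 1021 ± 81.4 TPM. Schlafen genes (7 of 8) summed to 3147 ± 49.7 TPM, led by Slfn2 at 1962 ± 192 TPM. Cathepsins, lysosomal proteases, had 11 of 22 detected and summed to 24785 ± 202 TPM, with Ctsd at 6663 ± 773, Ctss at 3589.9 ± 475 and Ctsz at 1947 ± 27 TPM. Subunits of the vacuolar ATPase, which acidifies lysosomes, had 18 of 24 detected and summed to 5369.9 ± 363 TPM. The polymerase genes Parp9 to Parp14 (5 of 5) summed to 1294 ± 53.4 TPM, led by Parp14 at 464 ± 38.1 TPM. Among Ms4a membrane proteins, 8 of 19 were detected, with Ms4a4c at 2019 ± 507, Ms4a6c at 1419.6 ± 79.9 and Ms4a7 at 1219 ± 87 TPM. Purinergic receptors (7 of 15 detected) summed to 639.5 ± 16 TPM, and cytosolic ribosomal proteins (80 of 83) to 50509 ± 3063 TPM.

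Among noncoding RNAs other than ribosomal RNA, also chosen after the values were seen, AW112010 stood at 3506 ± 943 TPM in the gene tables and 2658 ± 554 TPM in the second quantification (SD, n = 3). The nuclear RNAs Malat1 and Neat1 stood at 381 ± 118 and 111 ± 46.9 TPM, and Mir155hg, the host transcript of microRNA 155, at 92.5 ± 28.8 TPM. Gm10076 stood at 1299 ± 356 TPM in the gene tables and 1.82 ± 1.49 TPM in the second quantification, so its level is uncertain. In replicate 2, genes at 2-fold or more from both others included Ccl22 at 29.8, 126 and 32 TPM, Ccr7 at 4.16, 17.8 and 4.68 TPM, the fatty acid transporter Cd36 at 46.6, 390.2 and 111 TPM and the lipase gene Lpl at 129, 543 and 229.6 TPM in replicates 1, 2 and 3. Ch25h, which makes an oxysterol, stood at 48, 12.1 and 40.2 TPM in the same order. Without replicate 2 the varying genes numbered 5203.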
